A study of Mus musculus with 5287 samples.

How the data were processed

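Mesenchymal stromal cells, also called fibro-adipogenic progenitors, were sorted from 3 mouse tissues and profiled cell by cell with inDrops, a droplet method that captures polyadenylated RNA and tags each molecule with a unique molecular identifier (UMI). Per the labels' protocols, the sort gate was CD45 negative, CD31 negative, Sca-1 positive, PDGFRA positive and podoplanin positive. Lymph node was taken apart mechanically, whereas muscle and visceral adipose tissue were digested with enzymes. The labels gave 1940 cells from muscle, 1661 from visceral adipose tissue and 1686 from lymph node, in 1 library per tissue, and named no animals. Each tissue was therefore treated as 1 sample, and cells were never counted as replicates.

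The deposited table holds counts of UMIs per gene and cell, as whole numbers that were not normalized. The submitters' processing notes name TopHat2, SAMtools and the genome build mm10. The versions of these tools, the counting step, the annotation and any barcode or cell filter were not given in the sources used here. The table had 23725 genes, of which 16566 had at least 1 UMI in any cell, kept or not. Its columns added up to 99.1% of the UMIs stated in the labels. It held 0 mitochondrial genes, so the planned filter on mitochondrial UMIs could not be applied.

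Cells with 500 or more UMIs were kept. This left 1932 muscle, 1655 visceral adipose tissue and 1674 lymph node cells and dropped 26. UMIs were summed over the kept cells of each library and expressed as CPM, the standard scaling of counts to a common library sum. A gene was compared in a pair of libraries when it had 100 or more UMIs in the pair. Fold differences are ratios of CPM. An exact Clopper-Pearson interval at the 95% level was computed for each ratio given both sums, and it covers counting error only. A library sum of 0 was set to 3 UMIs, which makes the fold a lower bound at this gene minimum. With 1 library per tissue, no difference has a replicate check. No significance test was run and no p-value is given. Genes were counted by size alone, as at least 2-fold apart, which is no test.

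Gene lists for 36 programmes and cell types, the comparisons, the filters and the rule for naming genes were fixed before the data were examined. For each list and pair, the median log2 ratio of the measured members was set against 10000 random lists of the same size matched on mean expression, and its percentile describes these libraries only. A further list of salivary secretory genes was written after the library sums had been seen. The rule named, for each tissue, the 12 genes with the largest value of the smaller of the log2 ratios against the other two libraries, among genes at 100 or more CPM there. It left out ribosomal, mitochondrial and haemoglobin genes and predicted genes with Gm or Rik names. For each list and pair it named up to 4 members with the largest absolute log2 ratio among those at 20 or more CPM in either library. It also picked Il33, the 5 sort gate genes and the 5 leading genes of each cluster, of which the text prints some. Other genes named in the text are further list members, chosen after their values were seen. A withheld item is not reported here.

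Shares of cells with a UMI were computed after each cell was thinned at random to 1000 UMIs, with exact Clopper-Pearson intervals. Thinning left out 108 muscle, 61 visceral adipose tissue and 178 lymph node cells that were too shallow. Each library was clustered on its own with the Leiden algorithm in scanpy 1.11.5 and igraph 0.11.9 (2000 variable genes, 20 principal components, 15 neighbours, resolution 0.5, counts scaled to 10000 per cell). A cluster was named when at least 3 markers of a list were among its 50 leading genes and no other list held more of its first 10. The size of that gene window and the tie rule were set after the clusters had been seen. Scrublet, run through scanpy with an expected rate of 6%, called 30 doublets (0.570% of kept cells), which were kept in the main results. Other software was Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9, R 4.3.3 and edgeR 4.0.16, the last for TMM factors only. Coordinates are from GENCODE M21 on GRCm38 (mm10), matched by symbol.

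The ratio step was tested on simulated counts with 200 changed genes per comparison. For muscle against visceral adipose tissue, 100 of 100 genes changed 3-fold and 100 of 100 genes changed 6-fold were recovered as at least 2-fold apart in the right direction, and 0 of 8282 unchanged genes passed 2-fold. For muscle against lymph node, the recovered numbers were 98 of 99 at 3-fold and 100 of 100 at 6-fold, with 1 of 7919 unchanged genes past 2-fold. For visceral adipose tissue against lymph node, they were 100 of 100 at 3-fold and 100 of 100 at 6-fold, with 0 of 8020 unchanged genes past 2-fold. The intervals covered the true ratio for 95.6%, 95.7% and 95.3% of genes in the same order. The simulation draws counting error alone and holds no variation between animals.

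Alternatives covered the scaling (TMM factors, median-of-ratios size factors, totals without ribosomal genes, each cell weighted the same), gene minimums of 20 UMIs and 1 UMI, other cell minimums, removal of Scrublet doublets, thinning, and other clustering settings. Removal of cells rich in genes of another cell type, clustering without Il33 and clustering under other cell minimums were added after the data had been seen. Deeper cells weigh more in a sum, which is why equal cell weights were tried. The planned removal of clusters named for another cell type had nothing to remove. The deposited table of cell metadata was not used, because the labels give the same values. Near-identical genes, such as C4a and C4b, Hbb-bs and Hbb-bt, Hspa1a and Hspa1b, Csf2rb and Csf2rb2, and H2-K1 and H2-D1, can share reads, and their separate values are uncertain.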

Results

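The data describe stromal cells of lymph node, muscle and visceral adipose tissue from male B6 mice aged 8 weeks. These PDGFRA-positive cells make collagen, give rise to fat and scar tissue, and feed growth factors, chemokines and the alarmin IL-33 to neighbouring cells. The protocol text mentions cardiotoxin, a venom protein that injures muscle, without tying the injury to single libraries. Each library held between 1661 and 1940 cells. Total depth over kept cells was 4995019 UMIs in muscle, 5354360 in visceral adipose tissue and 3988012 in lymph node. The median kept cell had 2473 UMIs from 1238 genes in muscle, 3191 from 1557 in visceral adipose tissue and 2154 from 1046 in lymph node. There was 1 library per tissue and no replicate, so each fold compares libraries, and values in parentheses after a fold are exact 95% intervals for counting error only. Tissue and library could not be told apart, nor could tissue and mechanical dissociation in lymph node. Whether cardiotoxin injury differed between the libraries is not known, so an effect of injury could not be told apart either.

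Transcripts of the positive sort markers were present in all 3 libraries, and those of CD45 and CD31, the negative markers, were nearly absent. Red cell genes were not absent, at 404, 939 and 1215 CPM in muscle, visceral adipose tissue and lymph node, nearly all from a few cells. Ly6a, which encodes Sca-1, stood at 3136, 2237 and 2607 CPM in muscle, visceral adipose tissue and lymph node. Pdgfra, the receptor that marks fibro-adipogenic progenitors, stood at 812, 695 and 669.8 CPM in the same order. Podoplanin (Pdpn) stood at 121, 232 and 96.8 CPM and was 2.40-fold (2.14 to 2.69) higher in the visceral adipose tissue library than in the lymph node library. Pecam1, which encodes CD31, stood at 2.80, 2.80 and 2.76 CPM, and Ptprc, which encodes CD45, at 0.200, 0.374 and 0.752 CPM. After thinning to equal depth, a Ly6a UMI was found in 89.4% (87.9 to 90.8) of muscle cells, 80.7% (78.7 to 82.6) of visceral adipose tissue cells and 77.9% (75.8 to 80.0) of lymph node cells. A Pdgfra UMI was found in 51.3%, 47.4% and 45.7% of the same cells, and a Pdpn UMI in only 12.3%, 21.4% and 8.02%. The 12 general mesenchymal genes, among them Col1a2, Dcn and Sparc, made up 149442, 97525 and 131373 CPM in sum.

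The genes that set each library most apart from the other two were, in muscle, Angptl7, Prg4, Myoc, Hoxc10, Ret, Angptl1, Sfrp4, Mfap4, H19, Dkk2, Thbs4 and Col8a1. Myoc encodes myocilin, a secreted glycoprotein (chromosome 1, 162639155 to 162649693), and stood at 2556, 4.48 and 161 CPM in muscle, visceral adipose tissue and lymph node. Prg4, the joint lubricant lubricin, stood at 153, 3.36 and 8.27 CPM. Of the H19 UMIs in muscle, 59.7% came from 5 cells. In visceral adipose tissue the leading genes were Tcf21, Hp, Wt1, Col6a5, Sult1e1, Psat1, Trf, Agt, Avpr1a, Hoxa5, Aldh1a3 and Fndc5. They include transcription factors of visceral mesenchyme (Tcf21, Wt1) and secreted plasma proteins (haptoglobin, transferrin and angiotensinogen). Sult1e1, an oestrogen sulfotransferase (chromosome 5, 87575969 to 87591594), stood at 54.3, 2687 and 87.8 CPM, and Col6a5, a collagen VI chain, at 5.81, 1251 and 29.3 CPM.

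In the lymph node library the leading genes were Bpifa2, Smr3a, Chia1, Mucl2, Car6, Pip, Cst10, Scgb1b27, Rgs16, Dnase1, Stc1 and Csf2rb. Most of these encode secretory products of salivary and lacrimal glands, and their UMIs came from a handful of cells. Bpifa2 (chromosome 2, 154008265 to 154016079) stood at 1176 CPM, of which 5 cells held 91.3%. Without the 20 lymph node cells that held 2% or more of their UMIs in a list of another cell type, a choice made after the data were seen, the leading genes were Rgs16, Stc1, Csf2rb, Il6, Cxcl1, Has1, Cxcl10, Dnajb1, Nfkbiz, Zfp36, Hspa1a and Tmem176a. These include inflammatory mediators, the hyaluronan synthase Has1 and stress-response genes. All 12 leading genes of muscle and all 12 of visceral adipose tissue stayed the same without such cells. There were only 3 such cells in muscle and 4 in visceral adipose tissue, so the leading genes had little room to change. The lists that marked these cells did not include those of tendon, pericyte, Schwann cell, nerve sheath or mesothelial genes.

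**Figure D1:**
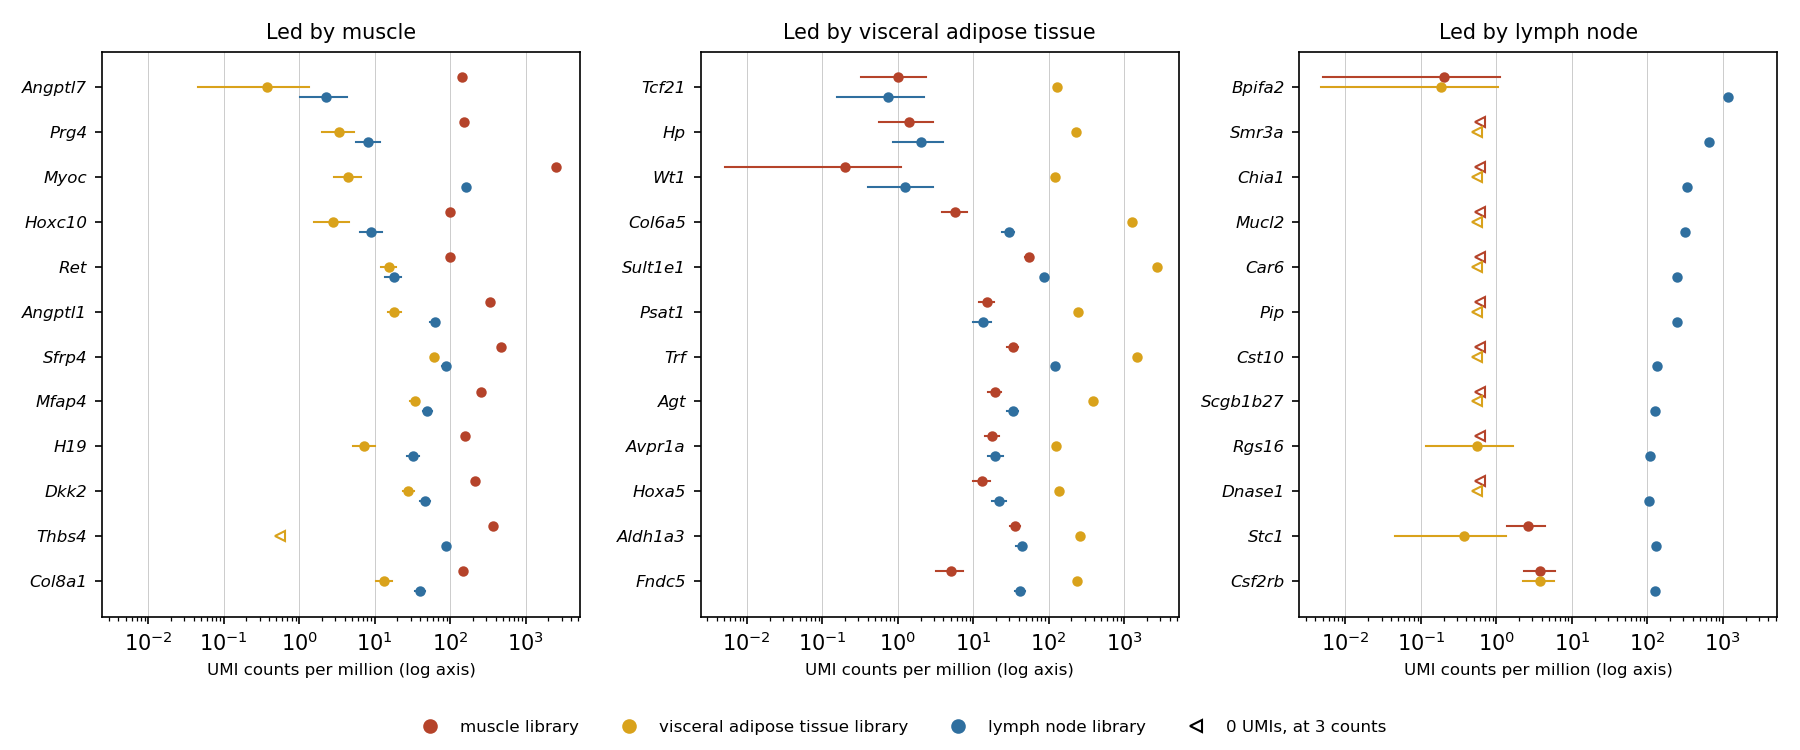
CPM of UMIs, on a log axis, of the 12 leading genes of each library over all kept cells, with 1 point per library and bars for exact 95% counting intervals. Open triangles mark a gene with 0 UMIs in that library, drawn at 3 counts; Myoc stood at 2556, 4.48 and 161 CPM in muscle, visceral adipose tissue and lymph node.

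The first comparison asks how stromal cells of muscle and of visceral fat differ. The muscle library carried more transcript for fibrillar collagens, for growth factor, BMP and WNT genes and for neural-related genes. Over all cells, the visceral adipose tissue library carried more for fat-cell differentiation, sterol synthesis and the immediate early response. Of 8523 genes compared, 283 were at least 2-fold higher in muscle and 422 at least 2-fold higher in visceral adipose tissue. This balance moved with the scaling, and TMM factors gave 316 and 362 genes.

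Matrix genes were higher in the muscle library. Of 25 fibrillar collagen and matrix genes measured, 7 were at least 2-fold higher in muscle, 0 were at least 2-fold higher in visceral adipose tissue and 18 lay within 2-fold. Their median log2 ratio, muscle over visceral adipose tissue, was 0.67 (percentile 100 of the random lists). Col1a1, the main chain of type I collagen, was 3.93-fold (3.86 to 3.99) higher in muscle, at 13579.7 against 3459 CPM. Col8a1, Thbs2 and Col12a1 were 11.3-fold, 6.27-fold and 6.25-fold higher. Tnc, which encodes tenascin-C, had no UMI in visceral adipose tissue and was at least 54.0-fold higher in muscle, where 5 cells held 62.9% of its UMIs. Tendon genes moved with the matrix genes, at 641 against 96.7 CPM in sum and a median of 4.55 over 4 measured members. Basement membrane genes went the other way by less. None of the 12 measured passed 2-fold, and their median was -0.40, with Lamb1 and Col18a1 leading. Among 15 matrix proteases and inhibitors, 1 was higher in muscle and 3 in visceral adipose tissue. The higher gene was stromelysin (Mmp3, 23.7-fold (16.1 to 36.3)), and the lower ones included Mmp19 and Mmp23. Genes of activated fibroblasts in regenerating tissue had 4 of 10 measured members higher in muscle, including Aspn (5.41-fold (4.96 to 5.91)) and Fap (3.04-fold (2.63 to 3.53)). Adam12, of the same list, was 13.2-fold (9.91 to 18.0) higher in visceral adipose tissue.

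Growth factor pathways also leaned to muscle. Of 28 growth factor, BMP and WNT genes, 13 were at least 2-fold higher in muscle, 3 in visceral adipose tissue and 12 within 2-fold, with a median log2 ratio of 0.84. Igfbp5, which binds insulin-like growth factors, was 19.1-fold (17.8 to 20.6) higher, at 2697 against 141 CPM. Ctgf, Wnt2 and the WNT inhibitor family member Dkk3 were 20.8-fold, 13.5-fold and 10.6-fold higher. Igf1, Sfrp1 and Fgf10 were 2.90-fold, 2.99-fold and 4.30-fold higher in visceral adipose tissue. Neural-related genes had 7 of 15 measured members higher in muscle and 1 lower. The adhesion molecule Ncam1 was 8.26-fold (4.97 to 14.6) higher, neurotrophin 3 (Ntf3) 4.38-fold (3.16 to 6.19) and the CGRP receptor subunit gene Calcrl 2.65-fold (2.13 to 3.33). The neurotrophin 3 receptor gene Ntrk3 was 6.75-fold (4.43 to 10.7) higher in visceral adipose tissue. Of 12 genes of the Dpp4 and Pi16 progenitor state, a reserve-like fibroblast state, 5 were higher in muscle and 7 within 2-fold, with Pi16 3.06-fold (2.86 to 3.28) higher. Within the progenitor-like clusters, 2 of 11 measurable members passed 2-fold, against 4 of the same genes over all cells. Their medians were 0.47 and 0.87. These clusters were named by genes of this same list, so a smaller difference within them may be built in, and no conclusion is drawn from it.

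Genes of fat-cell differentiation were higher in visceral adipose tissue. Of 16 adipogenic genes, 7 were at least 2-fold higher there, 0 in muscle and 9 within 2-fold. Pparg, the master regulator of adipocyte formation, was 3.27-fold higher, at 6.41 against 20.9 CPM. Agt, Apoe and Klf15 were 20.1-fold, 6.33-fold and 2.92-fold higher. Sterol synthesis genes were lower in muscle, with 3 of 15 past 2-fold and a median of -0.56. They were led by squalene epoxidase (Sqle, 2.90-fold (2.12 to 4.04)) and Idi1 (2.42-fold (2.05 to 2.88)). Antioxidant and xenobiotic genes had 3 of 16 higher in visceral adipose tissue, of which Cyp1b1 reached 9.88-fold (8.80 to 11.1). Immediate early genes, which respond within minutes to stimulation or handling, had 10 of 23 higher in visceral adipose tissue and a median of -0.61. Egr2, Fosb and Atf3 were 4.96-fold, 3.94-fold and 3.55-fold higher there. Within the progenitor-like clusters these medians turned to above 0 for the genes that could be measured there. They were 0.30 for 15 immediate early genes (the same genes over all cells -0.38), 0.05 for 9 sterol synthesis genes (-0.30) and 0.07 for 15 antioxidant and xenobiotic genes (-0.43), of which only Cyp1b1 passed 2-fold. For 5 adipogenic genes the median was 0.06 (-0.43), with none of the 7 that passed 2-fold over all cells among them.

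Transcription factors of body position differed in both directions, with 7 of 22 higher in muscle and 7 in visceral adipose tissue. Hoxa10 and Hoxc10, of the posterior Hox clusters that pattern the limb, stood at 51.9 against 0.747 CPM and 101 against 2.80 CPM. Meox2 was 32.2-fold (21.4 to 50.5) higher in muscle, and Tbx15 stood at 90.7 against 0.374 CPM. Wt1 stood at 0.200 against 121 CPM, and Tcf21 was 129-fold (55.0 to 398) higher in visceral adipose tissue, at 129 CPM. Among retinoid genes, Aldh1a2 was 2.76-fold (2.42 to 3.17) higher in muscle and Aldh1a3 7.22-fold (6.17 to 8.48) higher in visceral adipose tissue. Tendon genes were higher in muscle for 3 of 4 measured members, with Thbs4 at least 659-fold, Comp at 36.0 against 0.374 CPM and Tnmd 5.68-fold (4.36 to 7.49). Immune programmes differed gene by gene. Among 13 inflammatory chemokine and cytokine genes, 3 (Cxcl14, Cxcl9 and Il33) were higher in muscle and 3 (Cxcl10, Ccl2 and Ccl7) in visceral adipose tissue. Of 8 lymphoid stroma genes, Vcam1 alone passed 2-fold, 2.82-fold (2.43 to 3.29) higher in visceral adipose tissue. None of 8 antigen presentation genes passed 2-fold. Among 17 interferon-stimulated genes, 1 (Usp18) was higher in muscle and 1 (Irf7) in visceral adipose tissue. Among 11 complement genes, clusterin (Clu) was 23.1-fold (13.0 to 45.4) higher in muscle and C3 was 2.81-fold (2.69 to 2.93) higher in visceral adipose tissue.

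**Figure D2:**
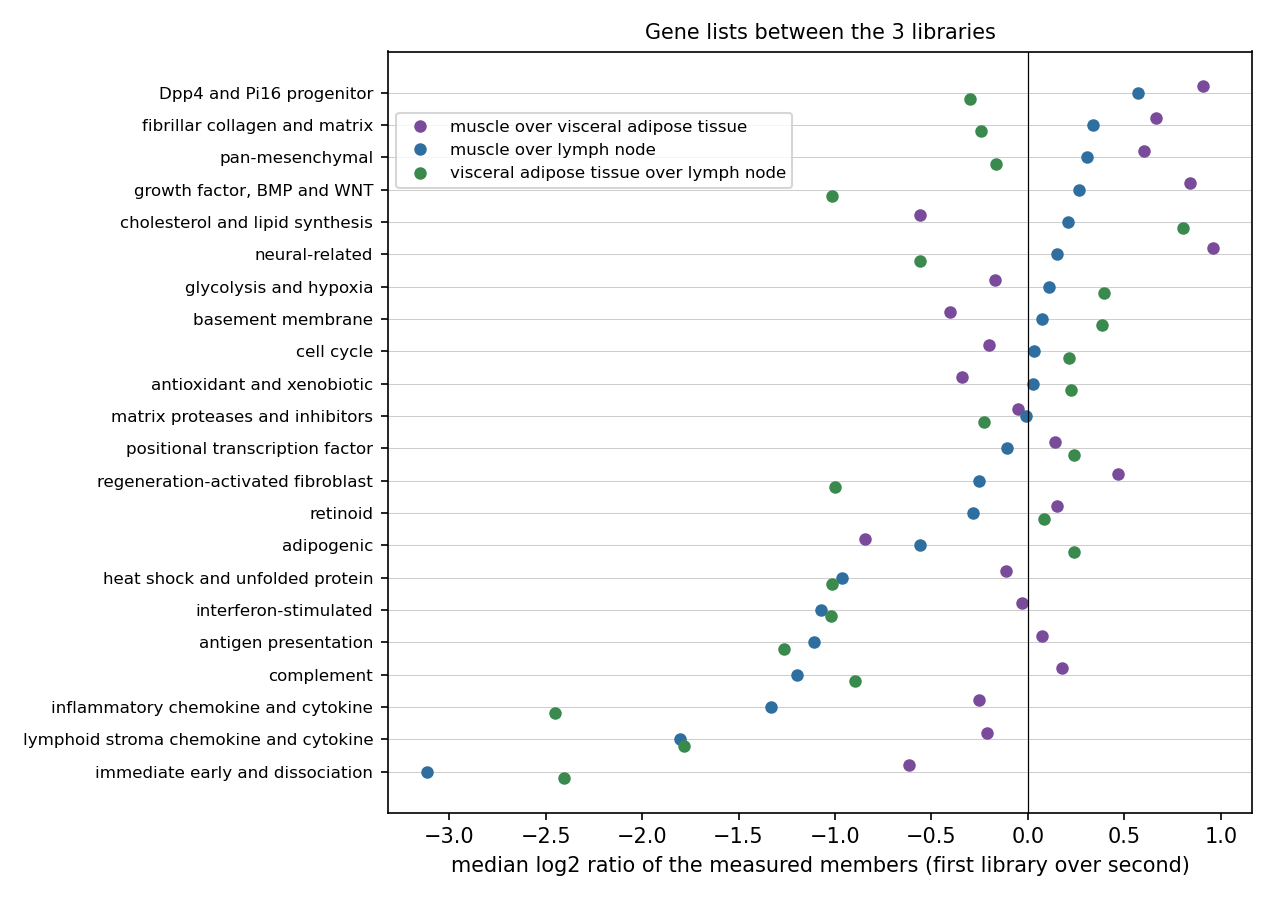
Median log2 ratio of the measured members of gene lists for the 3 pairs of libraries, with 1 point per list and pair. Lists with few measured members in any pair, such as those of tendon and red cell genes, are not drawn. Immediate early genes lay at -3.11 for muscle over lymph node and -2.41 for visceral adipose tissue over lymph node.

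The second comparison sets muscle stromal cells against those of the lymph node, where fibroblasts organise lymphocytes through chemokines. The lymph node library carried more transcript for lymphoid chemokines, inflammatory cytokines, complement, interferon response and antigen presentation. It also carried far more for immediate early and heat shock genes. Muscle was higher for several elastic-fibre and matrix genes and for posterior Hox genes. Of 7987 genes compared, 210 were at least 2-fold higher in muscle and 325 in lymph node.

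Genes that lymphoid stroma uses to guide lymphocytes were higher in the lymph node library. Of 8 measured, 7 were at least 2-fold higher there and 1 lay within 2-fold, with a median log2 ratio, muscle over lymph node, of -1.80. Cxcl13, which attracts B cells, was 6.11-fold (5.25 to 7.12) higher, Ccl19, which attracts T cells, 5.97-fold (5.24 to 6.82), and Cxcl12 4.45-fold (4.25 to 4.66). Vcam1, Icam1 and Enpp2 were 3.76-fold, 3.23-fold and 2.54-fold higher. Within the progenitor-like clusters Enpp2 was instead 3.71-fold (2.89 to 4.82) higher in muscle, and the median of 4 measurable list members was -0.89, against -1.75 for the same genes over all cells. Of 15 inflammatory chemokine and cytokine genes, 10 were higher in lymph node, 0 in muscle and 5 within 2-fold. Il6 (chromosome 5, 30013114 to 30019981) was 225-fold (109 to 561) higher, at 1.40 against 315 CPM. Cxcl1, a neutrophil attractant, was 43.5-fold (37.3 to 51.1) higher, at 32.8 against 1429 CPM, and Cxcl10 and Ccl7 were 48.7-fold and 11.8-fold higher.

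Innate and antigen-presenting programmes followed the same direction. Complement genes had 6 of 10 higher in lymph node, with C3 5.23-fold (5.02 to 5.44), C2 2.70-fold (2.49 to 2.92) and Clu 2.97-fold (2.56 to 3.45). Interferon-stimulated genes had 9 of 17 higher and a median of -1.07, led by Irf1 (6.13-fold (5.25 to 7.19)) and Iigp1 (5.33-fold (4.64 to 6.15)). Antigen presentation genes had 8 of 9 higher. B2m, the light chain of class I molecules, was 3.14-fold (3.06 to 3.22) higher, at 1695 against 5326 CPM, and the immunoproteasome subunit gene Psmb8 3.15-fold (2.52 to 3.98). Within the progenitor-like clusters, 3 of 7 measurable antigen presentation genes passed 2-fold, against 6 over all cells, with medians of -0.79 and -1.51. For 10 interferon-stimulated genes the counts were 3 and 4 and the medians -0.49 and -0.84. The medians of 8 complement genes were -1.15 and -1.19.

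All 23 immediate early genes had a ratio below 1 in muscle over lymph node, and 22 were at least 2-fold higher in lymph node. Their median was -3.11. Fosb and Fos, subunits of the AP-1 transcription factor, were 39.7-fold (34.8 to 45.5) and 14.7-fold (14.0 to 15.4) higher, at 45.6 against 1811 CPM and 369 against 5435 CPM. Atf3, Zfp36 and Egr2 were 34.7-fold, 27.9-fold and 17.9-fold higher. Heat shock and unfolded protein genes had 9 of 18 higher, led by the co-chaperone Dnajb1 (17.1-fold (15.3 to 19.1)). Within the progenitor-like clusters, 6 of 17 measurable members passed 2-fold, against 9 of the same genes over all cells, with medians of -0.62 and -1.06. Mt1 and Mt2, the metallothioneins, and Hmox1 were 3.67-fold, 3.60-fold and 5.44-fold higher in lymph node.

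Muscle was higher for 6 of 25 fibrillar collagen and matrix genes and lower for 1, with a median of 0.34. Those higher were Col8a1 (3.75-fold (3.16 to 4.47)), the crosslinking enzyme gene Lox (2.94-fold (2.34 to 3.70)), Fbln2, Vcan, elastin (Eln, 2.46-fold (2.32 to 2.60)) and Tnc, while Thbs1 was 3.45-fold (3.06 to 3.91) higher in lymph node. Tnc fell under 2-fold when each cell weighed the same. Among matrix proteases and inhibitors, Mmp3 was 6.63-fold higher in lymph node. Adipogenic genes had 6 of 16 higher in lymph node and 1 (Fabp5) in muscle, with Apoe 25.7-fold (23.7 to 28.0) and Cebpd 4.24-fold (3.97 to 4.52). Growth factor genes were split, with 4 higher in muscle, among them Sfrp4 (5.40-fold (4.83 to 6.06)) and Dkk2 (4.56-fold (3.90 to 5.35)), and 4 higher in lymph node, among them Fgf10 (8.71-fold (6.34 to 12.2)). Positional factors higher in muscle were 6 of 21, led by Hoxc10 (11.2-fold (7.98 to 16.2)) and Hoxa10 (8.99-fold (5.86 to 14.4)), and Nr2f1 was 7.04-fold (5.31 to 9.48) higher in lymph node. Aldh1a2, which makes retinoic acid, was 32.8-fold (20.9 to 54.8) higher in muscle. Acta2 and Tagln, contractile genes, were 16.5-fold and 7.25-fold higher in lymph node, where 5 cells held 43.0% and 41.8% of their UMIs. Neural-related genes were mixed, with Ramp1 4.40-fold (3.42 to 5.74) higher in muscle and the neuropeptide Y receptor gene Npy1r 5.31-fold (3.27 to 8.99) higher in lymph node. The 14 sterol synthesis genes and 12 basement membrane genes all lay within 2-fold, and of 12 glycolysis and hypoxia genes Vegfa and Hk2 were 3.16-fold and 2.58-fold higher in lymph node. Within the progenitor-like clusters, 3 of 12 basement membrane genes (Col15a1, Col4a2 and Col4a1) were at least 2-fold higher in muscle. So was 1 of 8 sterol synthesis genes measurable there (Hmgcs1).

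The third comparison sets visceral adipose tissue stromal cells against those of the lymph node, which often lies inside fat. The lymph node library was higher for the same immune and stress programmes and for many growth factor genes. Visceral adipose tissue was higher for sterol synthesis and for its own positional factors. Of 8220 genes compared, 401 were at least 2-fold higher in visceral adipose tissue and 345 in lymph node. This balance depended on the scaling. The median of all genes was 0.21, and TMM factors shifted log2 ratios by -0.20 and gave 283 and 443 genes. For muscle against lymph node the same shift was -0.11.

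Immediate early genes had 20 of 23 members at least 2-fold higher in lymph node and a median, visceral adipose tissue over lymph node, of -2.41. Zfp36, which limits cytokine messages, was 13.8-fold (13.1 to 14.6) higher, and Fosb 10.1-fold (9.41 to 10.8). Heat shock genes had 10 of 18 higher, with Hspa1a 18.7-fold (17.4 to 20.3) and Dnajb1 17.1-fold (15.3 to 19.0). Inflammatory genes had 10 of 16 higher in lymph node, with Il6 30.7-fold (23.4 to 41.0), Cxcl1 24.9-fold (22.2 to 28.0) and Cxcl9 23.8-fold (16.5 to 35.6). Lipocalin 2 (Lcn2) was the member higher in visceral adipose tissue. Lymphoid stroma genes had 5 of 8 higher in lymph node, with Ccl19 4.78-fold (4.25 to 5.37), Cxcl12 4.15-fold (3.98 to 4.34) and Icam1 4.70-fold (3.86 to 5.75). Cxcl13 was 8.91-fold (7.51 to 10.6) higher, although 5 cells held 71.1% of its UMIs in visceral adipose tissue. Complement genes were higher in lymph node for 5 of 11, with C7 5.77-fold (3.42 to 10.4) higher in visceral adipose tissue. Lymph node was also higher for interferon-stimulated genes in 9 of 17 and antigen presentation genes in 6 of 10. B2m was 3.75-fold (3.66 to 3.85) higher and Irf1 7.50-fold (6.37 to 8.88). Within the progenitor-like clusters the median of 9 measurable interferon-stimulated genes was -0.13, against -0.96 for the same genes over all cells. That of 7 inflammatory genes was -0.35, against -2.40. Of these 7, 3 (Il6, Cxcl1 and Il33) were at least 2-fold higher in lymph node, against 5 over all cells. Il6 stood at 0.819 against 180.4 CPM in these clusters and Cxcl1 at 26.2 against 981 CPM, visceral adipose tissue first. The median of 4 lymphoid stroma genes was -0.69, against -1.78, with Enpp2 2.08-fold (1.58 to 2.76) higher in visceral adipose tissue.

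Growth factor, BMP and WNT genes had 14 of 27 higher in lymph node and 2 higher in visceral adipose tissue. Igfbp5 was 16.6-fold (15.4 to 17.9) higher in lymph node and Dkk3 12.9-fold (7.56 to 23.6), while Igf1 was 3.81-fold (3.64 to 3.99) higher in visceral adipose tissue and Sfrp1 4.58-fold (4.23 to 4.97). Matrix genes were split, with 3 of 24 higher in visceral adipose tissue (Lox, Vcan and Eln) and 5 higher in lymph node, including Col1a1 (3.20-fold (3.15 to 3.26)) and Thbs2 (5.80-fold). Mmp3 was 157-fold (108 to 239) higher in lymph node. Sterol synthesis genes had 6 of 15 higher in visceral adipose tissue and a median of 0.81, led by Sqle (3.41-fold (2.37 to 5.04)) and Fdft1 (3.22-fold (2.38 to 4.43)). Adipogenic genes went both ways. Agt was 11.6-fold (9.71 to 13.9) higher in visceral adipose tissue, and Apoe, which carries lipid, 4.06-fold (3.92 to 4.21) higher in lymph node. Positional factors were also split, with 6 of 20 higher in each library. Hoxc8 was 8.74-fold (6.97 to 11.1) higher in visceral adipose tissue, and Meox2 was 17.2-fold (11.4 to 27.3) higher in lymph node. Aldh1a3 was 5.93-fold (5.06 to 6.98) higher in visceral adipose tissue. Regeneration-associated genes had 5 of 10 higher in lymph node and 1 (Adam12) in visceral adipose tissue, the former with Csrp2 (3.41-fold (2.77 to 4.22)) and Timp1 (2.22-fold (1.83 to 2.71)).

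Il33 encodes an alarmin that stromal cells release to act on regulatory T cells and other immune cells, and it was lowest in the visceral adipose tissue library. The gene lies on chromosome 19, 29925114 to 29960718 (GENCODE M21, GRCm38, as for the other coordinates). It stood at 72.7, 21.1 and 111 CPM in muscle, visceral adipose tissue and lymph node. Muscle was 3.44-fold (2.78 to 4.29) above visceral adipose tissue, and lymph node was 5.26-fold (4.27 to 6.53) above it. Lymph node was 1.53-fold (1.33 to 1.76) above muscle. At equal depth, an Il33 UMI was found in 7.24% (6.09 to 8.52) of muscle cells, 1.82% (1.22 to 2.60) of visceral adipose tissue cells and 9.56% (8.12 to 11.2) of lymph node cells. As a background, Pecam1 was found in 0.219% (0.0598 to 0.561), 0.251% (0.0684 to 0.641) and 0.201% (0.0414 to 0.585) of the same cells.

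**Figure D3:**
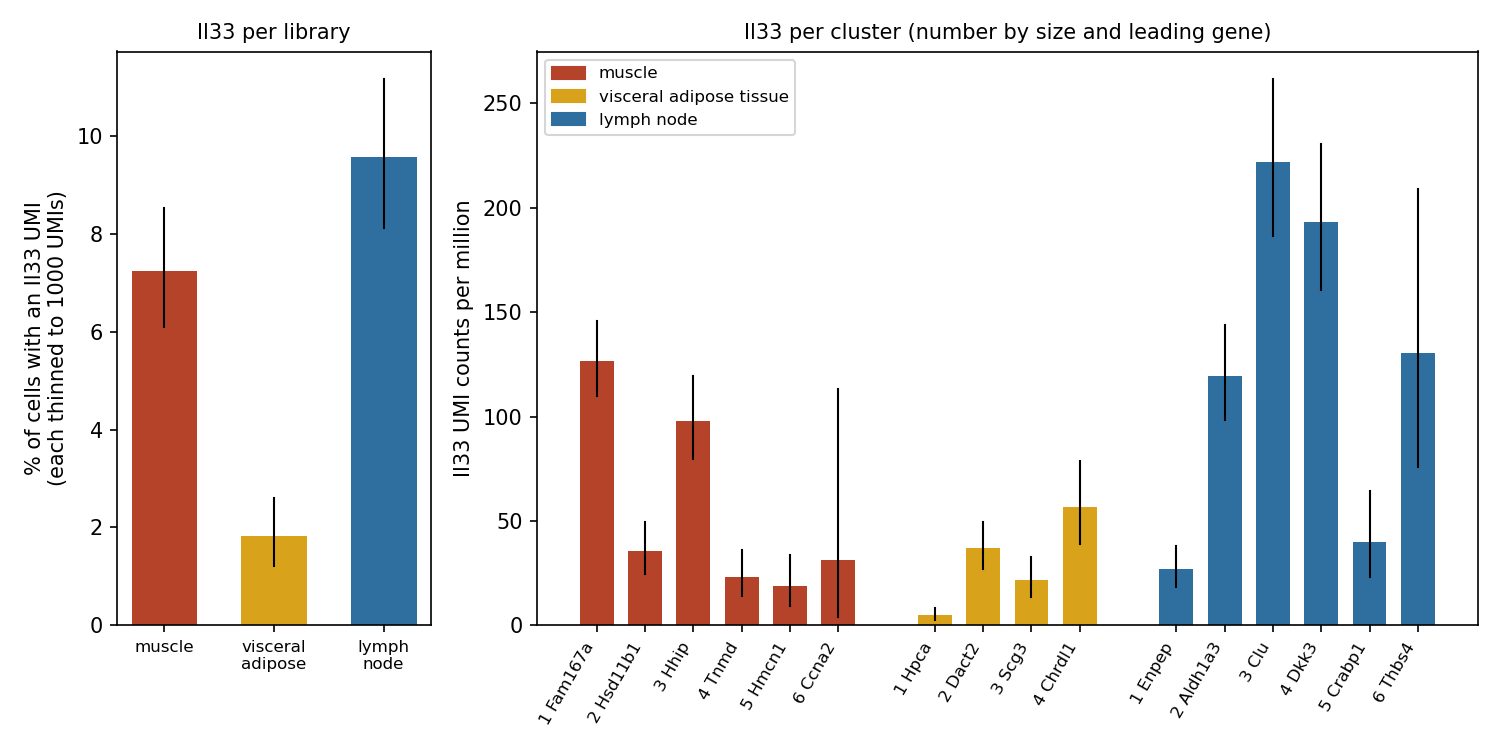
Left, percent of cells with an Il33 UMI after thinning to 1000 UMIs, per library, with exact 95% intervals; right, Il33 CPM in each cluster, numbered by size and marked with its leading gene. Visceral adipose tissue was lowest at 1.82% of cells.

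Clustering each library on its own separated a Dpp4 and Pi16 progenitor-like cluster in all 3, beside other clusters. That cluster held 34.0% of muscle cells, 24.0% of visceral adipose tissue cells and 24.1% of lymph node cells, and its Il33 level was 127, 36.9 and 119.6 CPM. Its share in visceral adipose tissue depended on the settings and fell to 0.483% when all libraries were clustered together and to 13.0% without the cell filter. In visceral adipose tissue the largest cluster, 43.1% of cells, was adipogenic-like (Agt, Apoe, Fabp4 and Plin2) and had the lowest Il33 level, 4.76 CPM (2.46 to 8.31). In lymph node a lymphoid stroma-like cluster with Ccl19, Enpp2, Cxcl12, Vcam1 and Icam1 held 17.7% of cells, and at resolution 1.0 a muscle cluster led by Cxcl13 (139 cells, 7.19%) took the same name. The lymph node cluster had the highest measured Il33 level, 222 CPM (187 to 262), and stood at 1086 CPM for Il6. The interval overlapped that of the lymph node cluster led by Dkk3, at 193 CPM for Il33 (161 to 231). Muscle clusters without a name were led by Hsd11b1, Col8a1 and Thbs4 (19.5% of cells), by Hhip and Abcc9 (16.6%), by Tnmd, a tendon gene (15.6%), and by Hmcn1, Meox1 and Prg4 (13.1%). A cycling cluster with Top2a and Mki67 held 21 muscle cells. Unnamed visceral adipose tissue clusters were led by Scg3 (22.7%) and by Chrdl1 (10.2%). The largest lymph node cluster, 28.3% of cells, was led by Enpep and Nrep. It had the lowest measured Il33 level of that library, 26.9 CPM (18.5 to 37.8), and held 18 of the 20 cells rich in genes of another type. Its Il33 interval overlapped that of the lymph node cluster led by Crabp1, at 40.1 CPM (23.3 to 64.2). Further lymph node clusters were led by Dkk3 and Mgp (16.8%), by Crabp1 (10.2%) and by Thbs4 and Col8a1 (2.93%).

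Transcripts of cell types outside the gate were scarce, apart from gland, red cell and fibre genes, which were carried mostly by few cells. No cluster was named for another cell type in any library, although groups of a few cells would not form a cluster. At resolution 1.0 a muscle cluster of 152 cells (7.87%) took the tenocyte name. In muscle, visceral adipose tissue and lymph node, summed CPM were 19.8, 9.34 and 16.5 for endothelial genes, 7.21, 5.42 and 1.76 for lymphatic endothelial genes, 7.21, 14.9 and 11.8 for myeloid genes and 2.20, 2.05 and 5.02 for lymphoid genes. Muscle precursor genes stood at 18.4, 17.0 and 21.3 CPM and mature adipocyte genes at 13.4, 5.23 and 25.8 CPM. Muscle fibre genes such as Acta1 stood at 149.7, 2.24 and 4.01 CPM, with 61.2% of the muscle UMIs in 4 cells. Haemoglobin and other red cell genes stood at 404, 939 and 1215 CPM, of which 4 cells held 98.7% in muscle. Among lists of cell types that share genes with stroma, those of pericytes stood at 140.1, 144 and 381 CPM, of Schwann cells at 539.7, 474 and 338, of nerve sheath at 75.5, 337 and 124, of tendon at 641, 96.7 and 154 and of mesothelium at 14.2, 149 and 16.0. Most of the mesothelial sum in visceral adipose tissue came from Wt1, at 121 CPM. The 10 salivary secretory genes stood at 23.2, 26.0 and 3676 CPM.

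**Figure D4:**
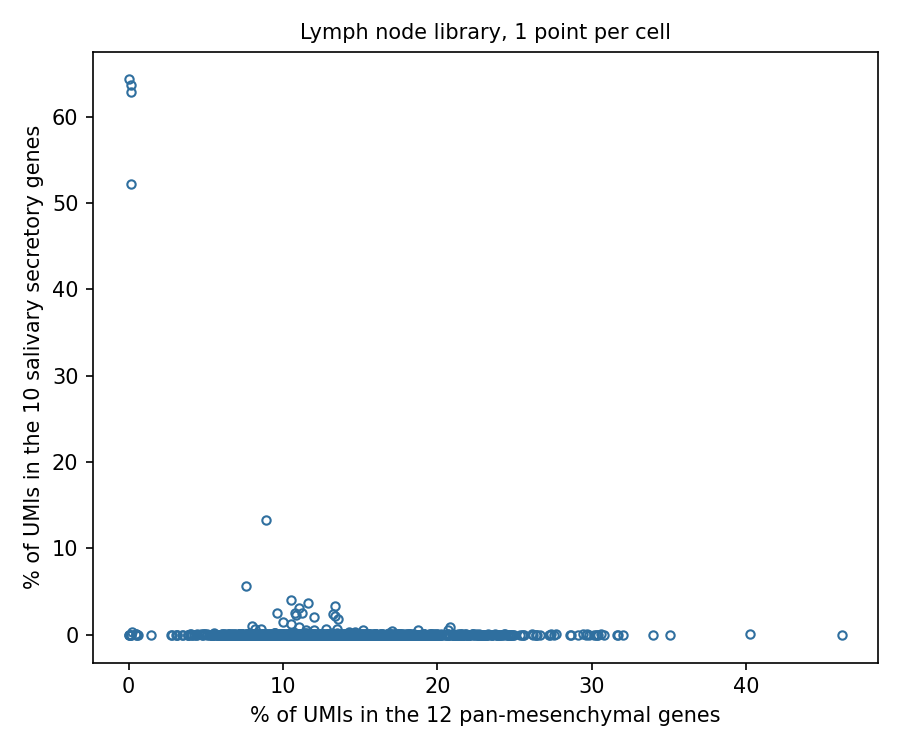
Percent of UMIs in the 10 salivary secretory genes against percent of UMIs in the 12 pan-mesenchymal genes, with 1 point per kept lymph node cell. The 4 cells with the most salivary UMIs had at most 0.152% of their UMIs in pan-mesenchymal genes and held 88.4% of the 14659 salivary UMIs.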

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

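The removal of cells rich in genes of another cell type, the clustering without Il33 and the clustering under other cell minimums were tests chosen only after the result was seen; the other alternatives were planned. Counts of genes at least 2-fold apart stayed within 1.5 times their main values under TMM factors, median-of-ratios size factors, totals without ribosomal genes, equal cell weights, the other cell minimums, and removal of Scrublet doublets or of cells rich in genes of another type. They moved with the gene minimum and with thinning. For muscle against visceral adipose tissue, 11604 genes were compared at 20 UMIs, 16051 at 1 UMI and 4996 after thinning, against 8523. At lower minimums the counts rose by more than the genes compared. Counting error is largest for genes with few UMIs, so the added counts cannot be read as tissue differences. How much of the rise it makes up was not measured. With a minimum of 20 UMIs, the counts were 670 and 837 for muscle against visceral adipose tissue, 576 and 679 for muscle against lymph node and 906 and 747 for visceral adipose tissue against lymph node, the first library of each pair first. With a minimum of 1 UMI, they were 1967 and 1914, 1592 and 1886 and 1958 and 2355. Here a sum of 0 stood at 3 UMIs, so a gene with 1 UMI against 0 counted as 2-fold higher in the library without it. The directions of these last counts are therefore not reliable, and part of their rise is by construction. With each cell thinned to 1000 UMIs, they were 148 and 220, 120 and 211 and 226 and 203. The balance between visceral adipose tissue and lymph node turned with the scaling, from 53.8% of such genes higher in visceral adipose tissue to 39.0% with TMM factors and 39.4% with median-of-ratios size factors.

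The order of the libraries for Il33 was the same at each thinning depth, and the shares rose with depth by construction. In muscle, visceral adipose tissue and lymph node they were 3.31%, 1.03% and 5.91% after thinning to 500 UMIs, 11.0%, 3.41% and 16.7% after thinning to 2000 UMIs and 13.5%, 4.77% and 17.2% without thinning. The share of Dpp4 and Pi16 progenitor-like cells moved to 31.2% in muscle and 28.5% in visceral adipose tissue with 10 principal components. It moved to 17.5% in visceral adipose tissue and 26.8% in lymph node with 30, and to 27.2% in lymph node at resolution 0.3. With all 3 libraries clustered together it fell to 0.483% in visceral adipose tissue, and without the cell filter to 13.0%. The cause was not tested. Cells with UMIs of 2 or more genes of another cell type list made up 2.33%, 1.03% and 1.25% of the libraries in the same order, against 0 cells in clusters named for another type, because the rule asks for less. In muscle at resolution 1.0, a cluster of 152 cells (7.87%) took the tenocyte name.

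Of 632 list medians recomputed under the alternatives, 486 stayed inside their counting interval, 146 moved outside it, and none past 2-fold changed sign, while 32 smaller ones did and 9 of 178 past 2-fold fell under it. Of 2412 values for named genes, 2146 stayed inside their interval and 266 moved, again with no sign change past 2-fold, though 28 of 1480 fell under it. Haemoglobin and salivary genes moved most when few cells were removed. The planned removal of clusters named for another cell type left every cell in place and gave no value. Depth limits rare transcripts, since a gene with 0 UMIs in a library is only bounded by 3 counts in the sum.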

Other observations

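The comparisons within progenitor-like clusters, the clustering without the cell filter and the tests set against each of the 3 patterns were chosen only after the result was seen, while the joint clustering was planned. The Dpp4 and Pi16 progenitor-like clusters were drawn in each library apart and named by the same marker list. Between them, tissue differences were smaller for some lists and larger for others. The share of this class in visceral adipose tissue moved with the settings, down to 0.483% with all 3 libraries clustered together and 13.0% without the cell filter. That these clusters hold the same kind of cell in each tissue was therefore not shown. In these clusters Fos stood at 271, 224 and 4504 CPM in muscle, visceral adipose tissue and lymph node, Il6 at 1.92, 0.819 and 180.4 CPM and Cxcl1 at 20.5, 26.2 and 981 CPM. Col1a1, the main collagen gene, stood at 8559.8, 3253 and 10947 CPM and the regulator Wt1 at 0, 103 and 0 CPM. The medians that follow compare the same genes in these clusters and over all cells. For visceral adipose tissue over lymph node, 20 immediate early genes had medians of -3.12 and -2.47. In contrast, 7 inflammatory genes had -0.35 and -2.40 and 9 interferon-stimulated genes -0.13 and -0.96. Of the 7 inflammatory genes, 3 and 5 were at least 2-fold higher in lymph node. Medians were also larger in size within the clusters for 16 growth factor genes (-0.70 and -0.47), 8 complement genes (-1.10 and -0.85) and 6 neural-related genes (-0.98 and -0.46). For 12 basement membrane genes they were 0.68 and 0.39, with 5 and 0 past 2-fold. For muscle over lymph node, 10 interferon-stimulated genes had -0.49 and -0.84, and 7 antigen presentation genes -0.79 and -1.51. For muscle over visceral adipose tissue, 15 immediate early genes had 0.30 and -0.38. Basement membrane genes, such as Lamb1 and Col18a1, had 3 of 12 measured members higher in visceral adipose tissue, and fibrillar matrix genes had 3 of 20 higher in muscle and 1 (Bgn) higher in visceral adipose tissue. Of the 7 adipogenic and 3 sterol synthesis genes past 2-fold between muscle and visceral adipose tissue over all cells, 0 and 1 could be measured there. Over the members that could, the medians were 0.06 for 5 adipogenic genes and 0.05 for 9 sterol synthesis genes, against -0.43 and -0.30 over all cells.

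Salivary secretory transcripts, such as those of Bpifa2 (1176 CPM) and Smr3a (652 CPM), were abundant in the lymph node library. The 5 richest cells held 91.6% of their UMIs, so a few gland cells in the sort are a candidate source, although the gate for Sca-1, PDGFRA and podoplanin should remove them. Free RNA in the droplets as the main source was argued against, since cells with under 2% of their UMIs in the list held 5.35%. The list still stood at 198 CPM (185 to 213) in those cells, against 23.2 and 26.0 CPM in the muscle and visceral adipose tissue libraries. Free RNA as a lesser source stays open. Expression by stromal cells as the main source was argued against too. Pan-mesenchymal genes made up 0.114% of the UMIs of the 4 richest cells and 12.6% of the median cell. Those 4 cells held 88.4% of the UMIs of the list. Low expression by stromal cells among the remaining cells was not tested. Of the 10 genes, only Amy1 stood above 1 CPM in muscle and visceral adipose tissue (23.0 and 25.8 CPM), and the list was drawn from genes that led this library.

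Immediate early genes were higher in the lymph node library across all of its clusters. A different mix of cell classes was argued against as the whole cause, because the median log2 ratio, muscle over lymph node, was -2.79 within progenitor-like clusters. Cells rich in genes of another type were argued against as well, with a median of -3.12 once they were removed. The way the tissue was taken apart stays open and may explain the pattern. The pair of libraries made with enzymes differed by -0.61, muscle over visceral adipose tissue, but no tissue was prepared both ways, so for lymph node dissociation and tissue cannot be told apart.

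Il33 was lowest in the visceral adipose tissue library. A different mix of cell classes was argued against as the whole cause, since within progenitor-like clusters the log2 ratio, muscle over visceral adipose tissue, was 1.78, or 3.44-fold (2.48 to 4.87). That test leans on how the class was drawn: in visceral adipose tissue Il33 stood at 29.4 to 47.8 CPM over the settings that clustered libraries apart, but the joint clustering left 8 cells with 2 UMIs (191 CPM), too few to compare. Shallow cells were argued against, since those of visceral adipose tissue were the deepest, with a median of 3191 UMIs (3118 to 3246) against 2473 and 2154. Library or tissue stays open, because there was 1 library per tissue, and a biological difference between tissues was not tested apart from it. Cardiotoxin injury stays open too, because the protocol text does not tie it to single libraries.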
